A study of Mus musculus with 5 samples.

How the data were processed

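RNA was measured by sequencing in 5 lines of NIH/3T3, an immortalised mouse embryonic fibroblast line. Each line carried an integrated gene for human histone H2A fused to the fluorescent protein EGFP. In 1 line the histone was wild type (wt), and in 4 lines, numbered 3, 6, 15 and 18 in the labels, it carried the T120D substitution, which puts an aspartate in place of a threonine of the C-terminal tail. Per the labels, the cells were grown in DMEM with 10% serum and 10 µg/ml gentamicin, total RNA was extracted with ISOGEN II, libraries were made with a stranded TruSeq mRNA kit, and the reads came from a MiSeq instrument.

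The authors deposited 1 table per line with RPKM values, read counts scaled to transcript length and to the mapped reads of the line, for 14454 gene symbols. Per the submitters' processing notes, the software Partek and the mouse build mm9 were used. The aligner, the gene annotation and the treatment of strand are not given in the sources used here, so values of overlapping genes, antisense pairs and multigene families are uncertain. The annotation available for gene order, transcript length and GC content was that of GRCm38, a different build. It was used for gene names, chromosome names and the order of neighbouring genes, and no coordinates are given. Of the 10052 tested genes, 10011 (99.6%) had a chromosome position and 9992 (99.4%) a transcript length there. Expression of the transgenes was not analysed here.

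RPKM tables hold no read counts. For genes with a single annotated transcript, low values in each line fell on multiples of the value of 1 read, which gave an estimated depth of 2530000 to 2730000 reads per line. Between 47.2% and 52.6% of such genes under 20 reads came within 0.05 reads of a whole number, where chance gives 10%. Some values were fractions of a read, so whole reads were not recovered for most genes and no count model was used to call genes. At this depth 1 RPKM of a transcript of 2000 bases corresponds to 5.1 to 5.5 reads. On simulated values of single-transcript genes the estimated depth was 1.0 times the true one.

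The 4 T120D lines were compared with each other before they were averaged. With the estimated reads of 283 single-transcript genes between 60 and 1000 reads, the chi-square per gene was 1.54 to 1.76 among lines 3, 15 and 18, 2.42 to 2.85 between line 6 and those lines, and 11.06 to 13.76 between the wt line and the T120D lines, where counting noise alone gives 1. Among 470 genes of 5 to 60 reads, lines 3 and 15 had a value of 1.07 (chi-square p = 0.132). Among the more abundant genes the value for lines 3 and 15 was above 1 (chi-square p = 1.05e-08). These reads rest on GRCm38 transcript lengths and estimated depths, so the level of 1 and both chi-square p-values are approximate. No pair was treated as 1 library deposited more than once. The 4 lines were counted as 4 samples because the labels number them separately; a spread above counting noise can also come from separate libraries of 1 culture. The labels do not say whether the lines were separate clones or separate cultures. Lines 3, 15 and 18 lay closer to each other than to line 6. They also shared lower values in a chromosome X segment described below, with medians of -0.95, -0.86 and -0.80 against 0.01 in line 6. They may therefore not be independent of each other, and n = 4 may overstate the number of independent lines. Adjusted p-values set the distance of the 1 wt line against the spread between the T120D lines, some of which may be technical. No spread between wt lines enters them.

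Values were analysed as log2(RPKM + 1), and genes with a mean of at least 1 RPKM over the 5 lines were tested. A log2 difference on this scale understates the change of genes of low expression. The mean of the 4 T120D lines minus the wt line was tested with limma (empirical Bayes with an intensity trend, two-sided) and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Since there was 1 wt line, the spread came from the T120D lines (3 residual degrees of freedom plus 5.99 from the prior), and the wt line was assumed to vary like them. An exact permutation of 1 line against 4 cannot go below a one-sided p of 0.2. Fold values given for single genes are ratios of RPKM. Counts of genes at least 2-fold apart and all other differences are on the log2(RPKM + 1) scale.

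Gene lists were tested with camera of limma with its preset correlation between genes of 0.01, for lists with at least 5 tested genes, with adjustment over the lists. The estimated correlation and fry were computed beside it. The 33 lists, fixed before the data were examined, covered G1 cyclins and CDK inhibitors, DNA replication, G2/M and mitosis, kinases of the H2A C-terminal tail with Polycomb components, H2A genes, developmental factors targeted by Polycomb, p53 targets, RAS-MAPK and immediate early genes, Wnt targets, YAP and SRF targets, contractile genes, extracellular matrix, matrix proteases and their inhibitors, interferon response, inflammatory cytokines and NF-kappaB targets, growth factors and receptors, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, MYC and nucleolar genes, the unfolded protein response with ATF4 targets, NRF2 targets, imprinted genes, adhesion and epithelial-mesenchymal genes, and housekeeping genes. The remaining lists held markers of adipocytes, cartilage and bone cells, macrophages, neural cells, skeletal muscle, epithelium and endothelium.

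The genes named in the text followed a rule fixed before the data were examined. It took the D cyclins; the 10 called genes with the largest positive and the 10 with the largest negative difference and all 4 T120D lines on one side of wt; up to 4 members with the smallest p of each list described; and, for each line, the 3 genes farthest above and the 3 farthest below the nearest of the other 4 lines. Genes outside the rule are named as chosen after their values were seen, and some genes that the rule takes are not reported here.

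The scan along the chromosomes, chosen after the data were seen, took the running median of the differences over 15 neighbouring tested genes and compared its largest value with 1000 shuffles of the gene positions. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5 RPKM, no filter on low values and a mean of at least 5 RPKM, median scaling, quantile normalization, leaving out each T120D line, limma without a trend and with robust estimation, and camera with an estimated correlation. A correction for transcript length and GC content and the removal of genes of 2 chromosome X segments were added after the data were seen.

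The tests were tried on simulated data with the design of 4 T120D lines against 1 wt line, 10052 genes and 200 changed genes, in 5 runs. Of the changed genes, 46.6% of those with a log2 size of 1 and 93.6% of those with a size of 2 were recovered, with 0 of the wrong sign. The mean number of false calls was 8.2 per run, and the highest was 11. With no changed gene, at most 1 gene was called. The simulated wt line varied like the T120D lines, with no difference of its own as a line or culture. The simulated gene counts therefore give no rate of false calls for a wt line that differs in that way. Of the simulated lists, 20 of 20 shifted by 0.6 and 0 of 120 unshifted lists were called. The simulated genes varied independently of each other. These list counts therefore give no rate of false calls for lists whose genes are correlated. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.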

Results

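Messenger RNA was profiled in 5 NIH/3T3 mouse fibroblast lines that express EGFP fused to human histone H2A, either wild type (1 line, wt) or with the T120D substitution (4 lines, numbered 3, 6, 15 and 18). The substitution replaces the threonine with an aspartate, which is often used to mimic a phosphorylated residue. The title of the series links phosphorylation of this threonine to oncogenic transformation and to cyclin D1. The design therefore sets the T120D lines against the wt line and asks which genes differ, cyclin D1 among them. Estimated depth was 2530000 reads in T120D line 3, 2710000 in line 6, 2660000 in line 15, 2630000 in line 18 and 2730000 in the wt line. Summed RPKM lay between 158613.7 and 160825.1, and 2163 to 2278 of the 14454 listed genes were at 0 in a line. The wt line had 10174 genes of at least 1 RPKM and the T120D lines 9926 to 9936. The wt group had no replicate, so each difference below rests on the distance of 1 line from the spread of the other 4.

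The T120D lines resembled each other more than any of them resembled the wt line. Across the 10052 tested genes, Pearson's r of log2(RPKM + 1) was 0.9708 to 0.9754 for the pairs of T120D lines, with 101 to 142 genes at least 2-fold apart on that scale. Against the wt line, r was 0.9147 for T120D line 3, 0.9262 for line 6, 0.9174 for line 15 and 0.9166 for line 18, with 698, 575, 683 and 665 genes at least 2-fold apart. These correlations are across genes, which are not independent replicates, and were not tested.

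Ccnd1, which encodes cyclin D1, was higher in all 4 T120D lines than in the wt line. Its expression was 121.2 ± 13.3 RPKM (SD, n = 4) in T120D and 46.5 RPKM in wt, a 2.61-fold difference. By line, the fold was 2.44 in line 3, 3.02 in line 6, 2.58 in line 15 and 2.39 in line 18. The log2 difference was 1.36 (SE 0.13, 95% confidence interval 1.06 to 1.65), with a limma adjusted p of 0.000381. The other D cyclins were not called. Ccnd2 was at 37.0 ± 1.61 RPKM (SD, n = 4) against 44.0 in wt (log2 difference -0.24, limma adjusted p = 0.188), and Ccnd3 was at 33.1 ± 2.27 RPKM against 25.01 (0.39, limma adjusted p = 0.0746). The genes of the E cyclins, which act with CDK2 at the start of DNA replication, were higher: Ccne1 was at 10.7 ± 2.25 RPKM against 3.94 and Ccne2 at 3.91 ± 0.713 RPKM against 1.15, with log2 differences of 1.23 and 1.18. Of the 15 tested members of the list of G1 cyclins and CDK inhibitors, these 3 genes were higher and 0 lower (4 and 0 adjusted over the list alone). As a list, the G1 genes were not called (camera adjusted p = 0.357). Without the filter on low values the calls of Ccne1 and Ccne2 ended, with limma adjusted p of 0.0892 and 0.0611.

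Beyond the cyclins, 1317 genes (13.1% of those tested) were called, 769 higher and 548 lower in T120D. All 4 T120D lines lay on one side of the wt line for each of the 1317 genes. The calling rule fixes this in advance, so it adds no support. A call needs a distance from wt larger than 1 of 4 lines can lie from their mean. Of the called genes, 453 had a log2 difference of at least 1 in size. On the log2(RPKM + 1) scale, 138 genes were at least 2-fold higher and 137 at least 2-fold lower in every T120D line. With a pseudocount of 0.1 RPKM these counts were 239 and 212, and at a mean of at least 5 RPKM 66 genes were lower by as much. The wt line lay below all T120D lines for 31.1% of tested genes and above all of them for 32.3%, where chance gives 20% each. Without the filter on low values 434 genes were higher, 653 of the 1317 calls remained, and the share of higher genes among the calls was 45.8%, against 58.4% with it. By limma without a trend 455 genes were higher and 361 lower.

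**Figure D1:**
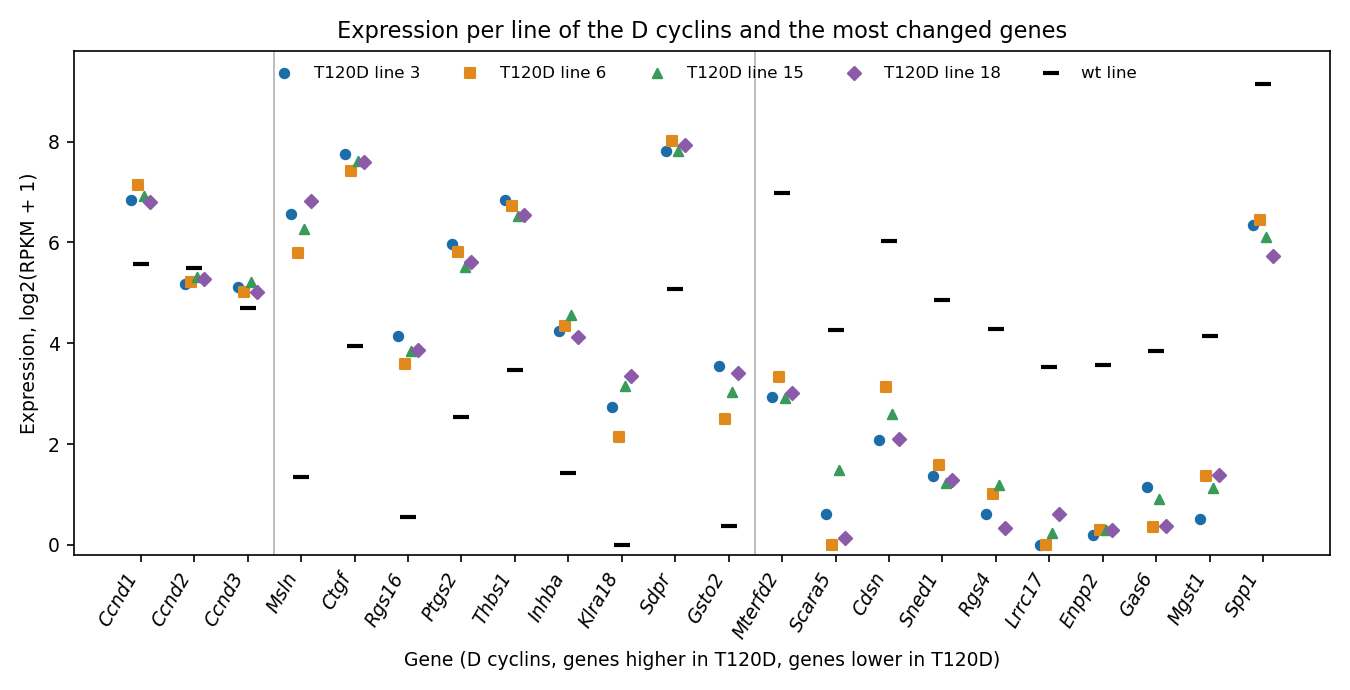
Expression of the D cyclins, of 9 genes with large positive differences and of the 10 with the largest negative differences, as log2(RPKM + 1). Colored points are the 4 T120D lines and black bars the wt line, which lies outside the range of the T120D lines for each of the 22 genes.

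The highest difference was that of Msln. This gene, which encodes the cell-surface protein mesothelin, was at 83.9 ± 24.2 RPKM (SD, n = 4) in T120D and 1.56 in wt, a log2 difference of 5.004 (SE 0.30, limma adjusted p = 5.61e-05). Ctgf, a matricellular growth factor gene, was at 192.3 ± 18.2 RPKM against 14.5, a 13.3-fold difference. Thbs1, encoding thrombospondin, was at 100.2 ± 10.6 RPKM against 10.1 (9.91-fold). Ptgs2, the inducible cyclooxygenase gene, was at 52.3 ± 7.48 RPKM against 4.78 (10.9-fold). Inhba, which encodes an activin subunit, was at 19.04 ± 2.66 RPKM against 1.68 (11.3-fold). Sdpr, a gene of caveolae, was at 237.8 ± 16.2 RPKM against 32.8 (7.26-fold). Rgs16, a regulator of G-protein signalling, and Gsto2, a glutathione transferase gene, were at 13.7 ± 2.34 and 8.01 ± 2.67 RPKM in T120D and at 0.471 and 0.290 RPKM in wt, a level that rests on few reads. Klra18 was at 6.52 ± 2.53 RPKM against 1.25e-10 in wt; it belongs to a family of similar genes between which reads can be split, and its call ended without the filter on low values (limma adjusted p = 0.0535). The log2 differences of these 9 genes ran from 2.75 to 5.004.

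Among the lowest differences, Spp1, which encodes the secreted protein osteopontin, was at 71.6 ± 15.2 RPKM (SD, n = 4) in T120D and 566.6 in wt, 7.92-fold lower. Mterfd2, a mitochondrial transcription factor family gene, was at 7.34 ± 1.14 RPKM against 125.1, and Sned1 at 1.59 ± 0.280 RPKM against 28.1, with log2 differences of -3.93 and -3.50. These 2 genes are direct neighbours on chromosome 1, 140 bases apart in the GRCm38 annotation. Cdsn, encoding corneodesmosin, was at 4.82 ± 2.11 RPKM against 64.0, and Mgst1, a microsomal glutathione transferase gene, at 1.20 ± 0.551 RPKM against 16.7. For 5 further genes the T120D mean was under 1 RPKM, a level of few reads: Scara5, a scavenger receptor gene (18.3 RPKM in wt), Rgs4 (18.3), Gas6, a ligand of the receptor Axl (13.4), Enpp2, which encodes autotaxin (10.9), and Lrrc17 (10.6). Their T120D means were 0.601, 0.769, 0.667, 0.209 and 0.173 RPKM. The 10 log2 differences ran from -3.93 to -2.99.

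The wt line also stood apart in the genes by which each line differed most from its nearest neighbour. It lay farthest above the other 4 lines for Mterfd2, Sned1 and Enpp2 (gaps of 3.65, 3.29 and 3.26 on the log2 scale) and farthest below for Msln, Ctgf and Thbs1 (4.44, 3.46 and 3.05). For single T120D lines no gap exceeded 1.88. Line 3 was farthest above for Atp5k, Eid3 and Zfp771 and below for Rpl36a, Ndufa3 and Olfr1317. Line 6 was farthest above for Snrpf, Prl2c3 and Gm2382 and below for Serf1, Gm6644 and Yipf2. Line 15 was farthest above for Rmrp, BC048507 and 2810410L24Rik and below for Tgoln2, Cyb5d1 and Atp5k. Line 18 was farthest above for Amn1, Snord22 and Spata24 and below for Ugt1a6b, Pcbd2 and Fbxo36. Except for Prl2c3, these T120D-line genes had at most 14.9 RPKM in any group.

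Of 33 gene lists, 28 had enough tested genes, and 10 were called with the preset correlation, 7 higher and 3 lower in T120D. With an estimated correlation 0 lists were called, the smallest adjusted p being 0.254. The test fry, which asks whether the genes of a list move one way and compares them with no other genes, gave an adjusted p under 0.05 for 11 lists. Among these were cholesterol synthesis (0.0451) and the unfolded protein response (0.0218), which camera did not call, and not the called extracellular matrix list (0.158). The directions of the 10 lists held under median scaling and quantile normalization.

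Genes of the contractile apparatus were higher. Of 16 tested members, 12 were higher and 0 lower in T120D (13 and 0 adjusted over the list alone), with a median log2 difference of 0.77 (camera adjusted p = 4.65e-10; adjusted p = 0.254 with an estimated correlation). Acta2, the smooth muscle actin gene, was at 88.1 ± 22.0 RPKM (SD, n = 4) against 18.7 in wt, and Cnn2, a calponin gene, at 133 ± 15.4 RPKM against 46.3. Tpm4, a tropomyosin gene, and Actn1, an actinin gene, had log2 differences of 0.88 and 0.86. Without the filter on low values the list's median, over 24 genes, was 0.46. Targets of the coactivator YAP and the factor SRF, which respond to actin dynamics, were also called. Of 20 members, 10 were higher and 1, Tgfb2, lower (12 and 3 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 3.71e-05; adjusted p = 0.254 with an estimated correlation). Besides Ctgf, Cyr61 was at 154 ± 25.7 RPKM against 28.6, Crim1 at 26.5 ± 1.92 RPKM against 5.75 and Amotl2 at 92.0 ± 6.43 RPKM against 38.2. Tgfb2 was chosen after its value was seen, as the 1 exception.

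Genes induced through RAS and MAPK signalling were also higher. Of 37 members, 14 were higher and 1, Ets2, lower (20 and 3 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 4.59e-08; adjusted p = 0.254 with an estimated correlation). Hbegf, encoding a ligand of the EGF receptor, was at 10.1 ± 1.78 RPKM (SD, n = 4) against 0.926, and Etv4, an ETS factor gene, at 7.89 ± 0.917 RPKM against 0.628. Dusp4, a phosphatase gene of the MAPK pathway, was at 9.74 ± 0.695 RPKM against 1.51 and Nr4a1, an immediate early gene, at 9.37 ± 0.579 RPKM against 1.63. Ets2 was named after its value was seen.

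Lists of proliferation and growth were also higher. In the DNA replication list, 14 of 40 members were higher and 0 lower (18 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 9.37e-09; adjusted p = 0.254 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 48.4 ± 3.98 RPKM (SD, n = 4) against 21.2, and Fen1, Mcm7 and Mcm4, which act at the replication fork, had log2 differences of 0.79, 0.80 and 0.77. Of 39 genes of G2/M and mitosis, 12 were higher and 0 lower (17 and 0 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 1.0e-06; adjusted p = 0.254 with an estimated correlation). They included Birc5, which encodes survivin, at 59.5 ± 4.48 RPKM against 32.1, Cdk1 at 25.2 ± 1.99 against 13.7 and Kif20a at 14.1 ± 1.54 against 6.97. Of 29 MYC and nucleolar genes, 12 were higher and 0 lower (22 and 0 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 3.48e-09; adjusted p = 0.254 with an estimated correlation). Odc1, the ornithine decarboxylase gene, was at 21.8 ± 1.01 RPKM against 10.9, and Nop56, a nucleolar protein gene, at 45.7 ± 4.08 RPKM against 23.8.

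Adhesion and epithelial-mesenchymal genes were called with a smaller shift. Among 29 members 8 were higher and 1, Snai2, lower (11 and 3 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00709; adjusted p = 0.306 with an estimated correlation). Cd44, a hyaluronan receptor gene, was at 65.7 ± 7.38 RPKM (SD, n = 4) against 28.6, and Pcdh18, Gja1 and Ncam1 had log2 differences of 1.24, 1.03 and 0.77. Snai2, a factor that promotes epithelial-mesenchymal transition, was named after its value was seen, and its call ended without the filter on low values (limma adjusted p = 0.089). This list was not called without the filter on low values (camera adjusted p = 0.0691) or at a mean of at least 5 RPKM (0.0777).

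Extracellular matrix genes moved both ways, with more of them lower in T120D. Of 40 members, 7 were higher and 15 lower (8 and 21 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.0265; adjusted p = 0.507 with an estimated correlation). Col6a1 and Col6a2, which encode collagen VI chains, were at 53.02 ± 4.48 and 39.6 ± 4.66 RPKM (SD, n = 4) against 192 and 126 in wt, 3.62-fold and 3.18-fold lower. In the other direction, Tnc, encoding tenascin C, was at 20.6 ± 2.004 RPKM against 3.00, beside Thbs1. The list was not called by limma without a trend (camera adjusted p = 0.105). Of 5 tested markers of cartilage and bone cells, 3 were lower and 0 higher (3 and 0 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 0.00153; adjusted p = 0.306 with an estimated correlation). They were Spp1, Matn2 at 3.81 ± 0.465 RPKM against 14.8, and Sox9, a chondrogenic transcription factor gene, at 13.3 ± 1.38 RPKM against 30.8. This list, too, was not called without the filter on low values (camera adjusted p = 0.0696), where its median over 13 genes was -0.15.

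Ribosomal protein genes were slightly lower. Among 49 members 14 were lower and 2 higher (18 and 4 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.85e-05; adjusted p = 0.254 with an estimated correlation). Rps19 was at 41.7 ± 1.96 RPKM (SD, n = 4) against 68.2 and Rps20 at 246 ± 7.76 RPKM against 350, log2 differences of -0.70 and -0.51. The 2 higher members, named after their values were seen, were Rpl30 and Rps29. By limma without a trend the calls of Rps20, Rpl30 and Rps29 ended, with adjusted p of 0.0768, 0.062 and 0.0742. Many ribosomal protein genes have processed pseudogenes that can share reads, so single members are uncertain.

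**Figure D2:**
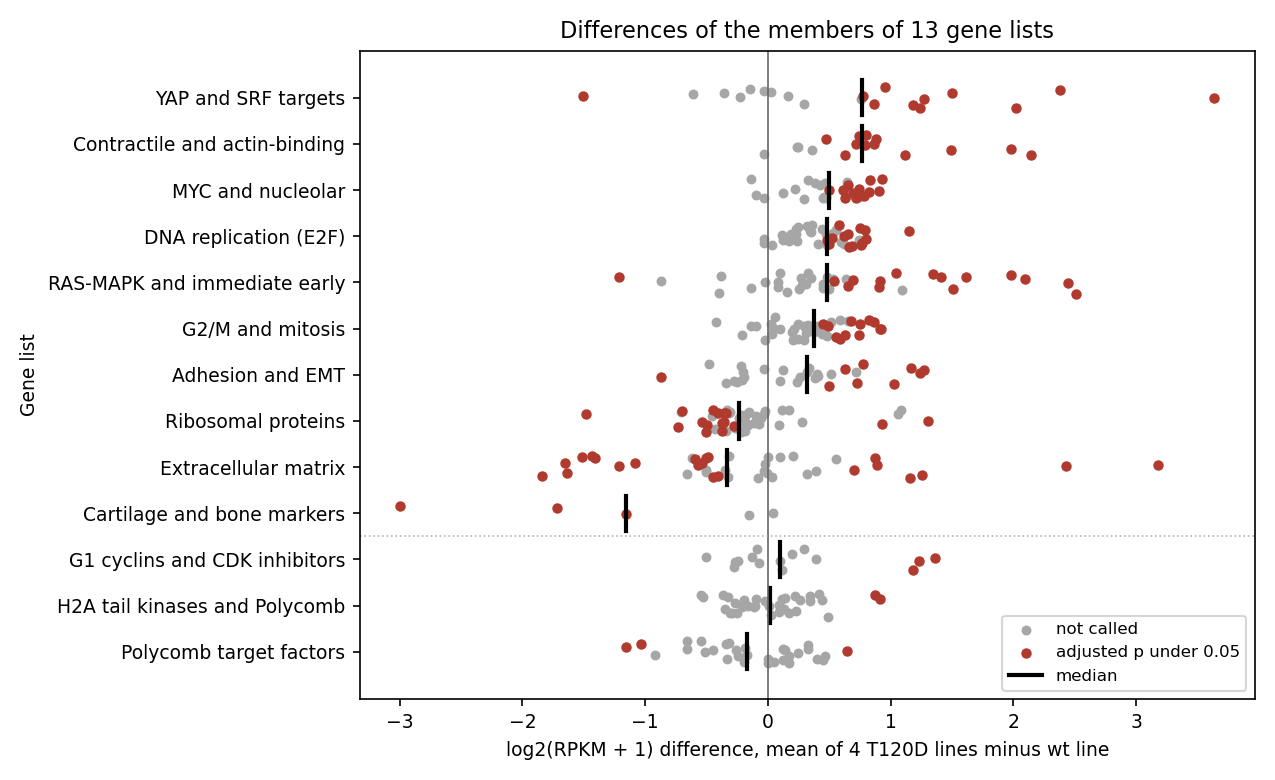
Log2 differences, T120D mean minus wt on the log2(RPKM + 1) scale, of the tested members of the 10 called lists (above the dotted line) and of 3 lists that were not called. Each point is a gene, red where its limma adjusted p is under 0.05, and black bars are list medians, which run from -1.16 for cartilage and bone markers to 0.77 for contractile genes.

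Genes of histone H2A and its modifiers were not called as lists. Over all tested genes, 13.1% were called. Of 34 tested genes for kinases of the H2A tail and Polycomb components, 2 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.666). These were Phc2, a Polycomb component, at 50.4 ± 2.77 RPKM (SD, n = 4) against 27.0, and Bub1, a mitotic kinase gene, at 6.81 ± 0.915 RPKM against 3.13. The call of Bub1 ended without the filter on low values (limma adjusted p = 0.0616). Of 20 listed endogenous H2A genes with values, 8 passed the filter on low values, and the others were not tested. Among these 8, 1 was lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.789). That is close to the share called over all tested genes. It does not show that expression of the endogenous H2A genes was unchanged. The list's mean and test pointed down while its median was 0.00. The lower gene, Hist3h2a, was at 1.25 ± 0.541 RPKM against 4.79. Its call ended without the filter on low values (limma adjusted p = 0.0903). Among 31 developmental factors targeted by Polycomb, 1 was higher and 2 were lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.25).

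Housekeeping genes were not called as a list (camera adjusted p = 0.475). Of 19 members, 3 were higher and 2 lower (5 and 3 adjusted over the list alone), among them Actb, encoding cytoplasmic actin, at 836 ± 61.9 RPKM (SD, n = 4) against 418, and Tfrc, the transferrin receptor gene, at 43.3 ± 2.13 RPKM against 19.3. Markers of some other cell types were low. The highest value in any line was 1.07 RPKM for skeletal muscle markers, 0.82 for epithelial and 0.64 for endothelial markers, with 0 genes tested in each list. For macrophages 1 marker was tested, Cd14, at 3.94 ± 1.23 RPKM against 1.71 and not called over all genes (limma adjusted p = 0.115), and for neural cells 2, Gap43 and Map2, with limma adjusted p of 0.159 and 0.409. Adipocyte markers reached 35.4 RPKM, and of 5 tested, 1 was higher and 0 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.48).

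Along chromosome X, neighbouring genes differed together. The largest running median of the comparison of the wt line with the T120D lines was 1.19, over 15 genes of chromosome X, while the highest in 1000 shuffles of gene positions was 0.791 (permutation p = 0.001, the smallest these shuffles can give). In the same scan with each T120D line set alone against the other 4 lines, the largest running median of the others minus the lone line also lay on chromosome X, at 0.489, -0.537, 0.511 and 0.449 for lines 3, 6, 15 and 18 (permutation p of 0.001, 0.001, 0.001 and 0.002). The segment from Sat1 to Mid1 held 35 tested genes with a median log2 difference of 0.63. The median was 0.73 in T120D line 3, 0.75 in line 6, 0.74 in line 15 and 0.70 in line 18. In this segment 27 genes were higher and 3 lower than in wt in all 4 T120D lines. Of its genes, 17 were called higher and 0 lower. The called genes included Rbbp7, a histone chaperone gene at 119 RPKM against 38.9, and Tmsb4x, a thymosin gene at 336 RPKM against 108. A different segment, from Sept6 to Apln with 17 tested genes, had a largest running median of -0.66, in size past the level of 0.637 set by the upper 5% of the shuffles and below the highest shuffle. It had medians of -0.95, -0.86 and -0.80 in lines 3, 15 and 18 and 0.01 in line 6. In it 3 genes were called lower and 0 higher, Lamp2, Rpl39 and Nkap; each of these calls ended in at least 1 alternative setting. Rbbp7, Tmsb4x and the genes of this second segment were named after their values were seen. Without the genes of both segments 1299 genes were called. The second segment is part of a run of 106 genes on proximal chromosome X, described below. Most genes of that run were not removed.

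**Figure D3:**
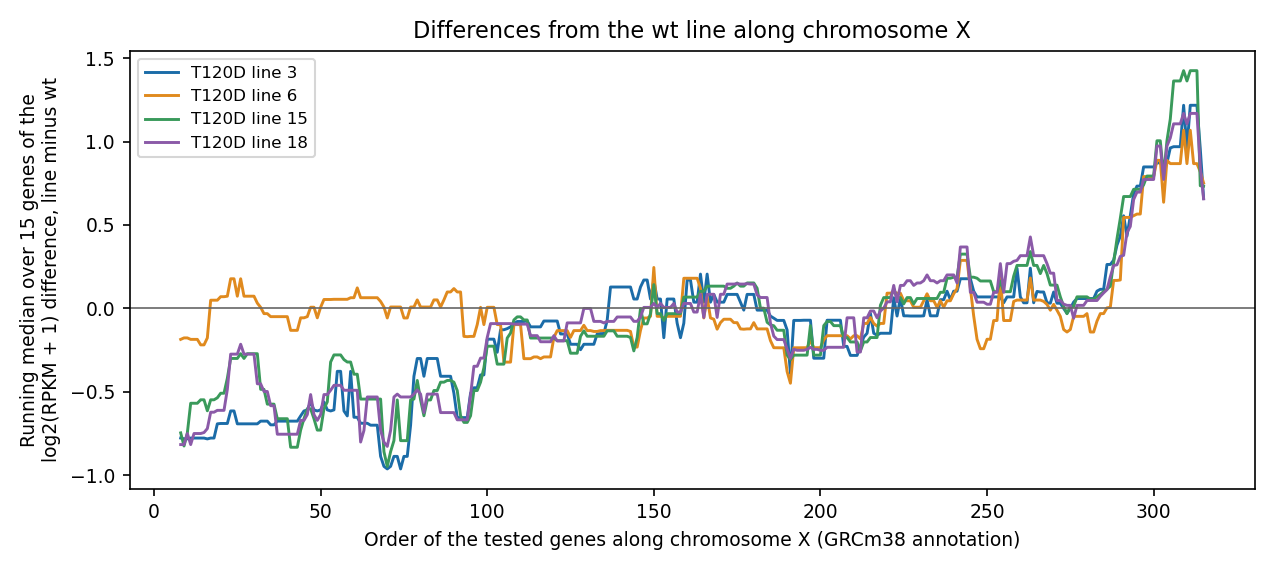
Running median over 15 tested genes of the log2(RPKM + 1) difference of each T120D line from the wt line, in gene order along chromosome X in the GRCm38 annotation. Lines 3, 15 and 18 lie below 0 at the left end while line 6 lies near 0, and the 4 lines rise together at the right end, where the median over the segment from Sat1 to Mid1 is 0.63.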

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

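The scan along the chromosomes, the test of genes on proximal chromosome X and the split of the lines were chosen only after the results were seen. The test of low genes in the segment from Sat1 to Mid1 and the correction for transcript length and GC content had their predictions written before their results were known.

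Among 178 values over the 4 T120D lines, 8 had 1 line far from the other 3 by Dixon's test, which chance gives for about 5% of such groups. Of these, 3 belong to genes chosen because a line stood apart. They were Ndufa3 in line 3, at 2.27 RPKM against 6.46 to 7.41 in the other T120D lines, 2810410L24Rik in line 15, at 2.42 RPKM against 0.865 to 0.927, and Fbxo36 in line 18, at 0 against 1.23 to 1.32 RPKM. The 4 other genes were Enpp2 in line 3, at 0.144 RPKM against 0.228 to 0.234, Mcm7 in line 3, at 20.80 RPKM against 23.83 to 24.04, Trp53inp1 in line 3, at 9.07 RPKM against 7.03 to 7.22, and Gja1 in line 6, at 38.4 RPKM against 45.6 to 46.7. The remaining value was the median difference from wt of the chromosome X segment from Sept6 to Apln, 0.01 in line 6 against -0.95 to -0.80 in lines 3, 15 and 18.

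For the chromosome X segment from Sat1 to Mid1, no shuffle of 1000 reached the observed running median (permutation p = 0.001, highest 0.791), which argues against chance runs of changed genes there. The running median of the segment from Sept6 to Apln, -0.66, was in size past the level of 0.637 set by the upper 5% of the shuffles and below the highest. For the first of these segments, a difference in dosage or activity of a chromosome piece between the wt line and the T120D lines may account for the pattern, but among 9 genes too low for the scan 6 were higher in T120D, against 1399 of 2781 elsewhere (one-sided exact Fisher p = 0.26), too few to decide. On proximal chromosome X, 106 genes picked from lines 3, 6 and 15 alone had a median of wt minus line 18 of 0.593. This was above the highest of 10000 random gene sets (0.21, permutation p = 0.0001, the smallest these sets can give). The random sets were scattered genes and not runs of neighbours, so this permutation p may be too small. The 106 genes include the segment from Sept6 to Apln, found in a scan that already used line 18, so the test is not independent of it. A large segment lower in lines 3, 15 and 18 than in wt and line 6 stays a hypothesis. The median of wt minus line 6 was -0.008, but the genes were picked for high values in line 6, which biases it. Copy number was not tested, nor was an effect of T120D on the first segment apart from the line.

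For the 1317 called genes, a trend with transcript length or GC content that differs between libraries is argued against: 1255 of the calls remained in the same direction after each line was corrected for it. Set alone against the others, each T120D line gave 0 calls with limma (169 to 202 genes at an unadjusted p under 0.05), against 1317 for the wt line (2869). In those splits the wt line is among the other 4 and widens their spread, so that few calls could be made and the 0 is no measure of chance. With 5 splits of the lines, of which 1 gave as many calls, the share cannot fall under 0.05. A difference of the wt line or its culture that is unrelated to T120D cannot be told apart from an effect of the mutation, because there was 1 wt line, and the mutation stays open as the biological explanation.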

How the results depend on the processing

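The corrections for transcript length and GC content, the removal of chromosome X genes and the alternatives for pairs of lines were chosen after the data were seen. The log2 difference of Ccnd1 stayed between 1.286 and 1.397 over 13 alternatives, with limma adjusted p of 0.000199 to 0.0215. Of 280 values for the 22 other D cyclins and most changed genes, 279 kept direction and call and 1 lost its call, Klra18. A further 125 genes were followed, taken from the lists by the rule or chosen after their values were seen. Not all of them are named here. Of their 1607 values, 1523 kept both, 77 lost the call, 7 gained it and 0 reversed. Eef1a1 became 0 under quantile normalization. Without the filter on low values 434 genes were higher, against 769, and 653 of the 1317 calls remained. Without a trend 455 genes were higher and 361 lower, against 769 and 548. Genes at least 2-fold higher in every line numbered 239 with a pseudocount of 0.1 RPKM, against 138, and genes at least 2-fold lower 212, against 137, or 66 at a mean of at least 5 RPKM. The lowest r between T120D lines exceeded the highest r with wt by 0.0446, and by 0.0226 without the filter. With an estimated correlation 0 lists were called, against 10. Leaving out 1 T120D line gave 955 to 1382 calls and 10 to 12 lists. Quantile normalization turned the sign of 1 of the 1317 genes. The cause of these changes was not tested, except that higher filters leave fewer genes. No paired analysis was possible because the groups share no replicate number. Depth limits genes near 1 RPKM, about 5.1 to 5.5 reads for 2000 bases.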

Other observations

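The test of the list of quiescence genes had its prediction written before its result was known. It was added after the report's lists had been tested, and its camera p-values were not adjusted over lists. They cannot be compared with the adjusted p-values of the other lists. With an estimated correlation, the unadjusted camera p was 0.0141 for the DNA replication list and 0.0184 for the YAP and SRF list. After adjustment each of these lists had a camera p of 0.254.

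Several lists that were not called held genes that differed in opposite directions. Of 34 growth factors and receptors, 7 were higher and 9 lower in T120D (8 and 11 adjusted over the list alone; camera adjusted p = 0.48). Pdgfra, encoding a PDGF receptor, was at 12.7 ± 1.72 RPKM (SD, n = 4) against 43.5 in wt. The receptor gene Axl was higher, at 135 ± 3.64 RPKM against 78.2, while its ligand gene Gas6 was lower. Of 20 matrix proteases and inhibitors, 5 were higher and 5 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.579): Plaur, the urokinase receptor gene, was at 32.3 ± 5.05 RPKM against 6.83, and Timp3, a metalloprotease inhibitor gene, at 35.3 ± 5.32 RPKM against 94.6. Among 26 inflammatory genes 5 were higher and 7 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.463). Cxcl12, a chemokine gene, was at 6.21 ± 1.73 RPKM against 42.8 and the complement gene C3 at 1.28 ± 0.180 RPKM against 7.93, whereas Ptgs2 was higher. None of 14 interferon response genes was called with limma (0 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.666). Irf1 lay at the limit, with a log2 difference of -0.69 (limma adjusted p = 0.0501). It was called lower by limma without a trend (adjusted p = 0.0455) and with robust estimation (0.0497). After the correction for transcript length and GC content it was also called (limma adjusted p = 0.041).

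In the list of the unfolded protein response and ATF4 targets, 12 of 35 members were higher and 5 lower (15 and 5 adjusted over the list alone; camera adjusted p = 0.113). The higher genes included the chaperones of the endoplasmic reticulum Calr, at 350 ± 19.6 RPKM (SD, n = 4) against 205, and Hsp90b1, at 182 ± 4.597 RPKM against 113. The lower ones included Ddit3, which encodes CHOP, at 13.95 ± 1.17 RPKM against 56.8, and Trib3 at 10.9 ± 0.618 RPKM against 37.9. Of 27 NRF2 targets, 1 was higher and 5 were lower (2 and 7 adjusted over the list alone; camera adjusted p = 0.25); Gstm1, a glutathione transferase gene, was at 3.65 ± 0.693 RPKM against 26.4, and Txnrd1, the thioredoxin reductase gene, at 84.7 ± 6.67 RPKM against 42.3. In the glycolysis and hypoxia list, 1 of 31 members was higher and 6 were lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.17). Oxidative phosphorylation had 5 higher and 1 lower of 47 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0736, and 0.0305 without line 3 and 0.0479 without line 6), and cholesterol synthesis 2 higher and 0 lower of 22 (2 and 0 adjusted over the list alone; camera adjusted p = 0.0887, and 0.0379 without the filter on low values). Of 15 imprinted genes, 0 were higher and 6 lower (0 and 6 adjusted over the list alone; camera adjusted p = 0.0887, and 0.0479 without line 6), with a median of 0.02 and a mean of -0.43; Dlk1 was at 31.5 ± 16.5 RPKM against 152, and its call ended without the filter on low values (limma adjusted p = 0.101). Among 26 p53 targets 4 were higher and 3 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.666), with a positive median and a negative mean, and Mdm2 was at 40.7 ± 1.96 RPKM against 22.2. For 9 Wnt targets 1 was higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.979), with a positive median and a negative mean, and Wisp2 was at 26.0 ± 3.78 RPKM against 66.1.

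The higher contractile, YAP, immediate early and replication genes may reflect a wt culture nearer to growth arrest than the T120D cultures, for example a denser one. A list of 30 genes of quiescence, of which 6 are also in the other lists, was lower in T120D than other genes (camera p = 5.58e-08, and p = 0.00856 with an estimated correlation), with 13 genes lower, 1 higher and a median of -0.56. Txnip, a glucose-regulated gene, was at 10.9 ± 1.82 RPKM (SD, n = 4) against 43.4, Pik3ip1 at 2.11 ± 0.274 RPKM against 7.19 and Ccng2 at 4.72 ± 0.590 RPKM against 11.5, named after their values were seen. The result is consistent with a difference in growth state, as a hypothesis, but a T120D histone that drives growth would give the same direction, and the labels state no cell density. Whether the culture or the mutation sets that state was not tested. The camera p-values of the quiescence list were unadjusted, so they do not set it apart from the other lists.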
